A study of Mus musculus with 6 samples.

How the data were processed

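The series measured gene expression in mouse striatum with an Affymetrix whole-transcript array. Per the labels' protocols, tissue punches were taken from the dorsal striatum of male mice at postnatal day 17, frozen, and extracted for RNA, which was labelled with biotin and hybridised to 1 array per sample. The labels place 3 samples in a control group, in which Mapk3 is null and Mapk1 is floxed, and 3 in a mutant group of the same genotype that also carries Drd2Cre. Mapk3 and Mapk1 encode the kinases ERK1 and ERK2, and Drd2Cre is a Cre recombinase driven by regulatory sequence of the dopamine D2 receptor gene, so that Mapk1 is removed where Cre is made. The labels call the samples biological replicates and do not say whether each came from 1 animal, so p-values measure the spread between these samples.

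The deposited values are on a log scale, read as log2, 1 per probe set and array, and were made by the authors. The submitters' processing notes name RMA and the Transcriptome Analysis Console, without versions. RMA subtracts background, normalises arrays against each other and summarises the probes of a set on the log2 scale. The base of the logarithm was taken from RMA and is not stated with the values, and the variant and scaling of RMA are not given in the sources used here. Fold differences in the text hold for base 2. The annotation and genome build that the authors used are not given in the sources used here. The medians of the 6 arrays over all probe sets lay between 5.82 and 5.92, and the highest values between 19.6 and 19.8, which is high for RMA. Values of every probe set were read as deposited, with no centring by gene. Beyond those noted beside their values, the genes of the text with a group mean below the negative control median of 6.65 were Ankk1, Chodl, Cux2, Gm4894, Htr3a, S100a8, S100a9, Slc18a3, Tmprss5, Trib3, Ttr, Upb1 and Xist, and their differences are not exact sizes.

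The table held 72688 probe sets. Of these, 6732 were array controls, 30638 were annotated to 1 gene symbol, 2176 to several and 33142 transcript probe sets to none. Gene names came from the platform's annotation as given by GEO. Its gene identifiers were compared with RefSeq genes of assembly GRCm38.p6, where 22596 identifiers matched and 0 symbols changed. That reference also gave the order of neighbouring genes. No coordinates are printed, because the build behind the array annotation is not named. Each gene was represented by the probe set with the highest mean over all 6 arrays among those annotated to that symbol alone, which gave 30176 genes. For 354 genes there were several probe sets, and for 0 of them did the probe sets disagree, that is, differ in direction with both past an unadjusted p of 0.05. Probe sets with several or no symbols stayed out of the test by gene. No probe set was listed under the symbols Mapk1, Mapk3 or Adora2a, so these genes were not analysed here, and the planned check of the labels by Mapk1 expression could not be made.

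Mutant and control arrays were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with a constant prior, with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. No filter on dim probe sets was used. A second, descriptive count took genes with an unadjusted p under 0.05 and a difference of at least 1.5-fold. Standard errors given with a difference are those of the moderated fit. Every adjusted p in the text is limma's unless another test is named. With 3 arrays in each group an exact permutation test of a single gene could not go below 0.1.

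Before the data were examined, 31 gene lists were fixed for signalling pathways, neuron classes, other cell types, neighbouring regions and cellular functions, together with the tests, the alternatives and the rule for naming genes. Of their 526 different symbols, 466 were measured. The 28 lists with at least 5 measured members, sex-linked genes excepted, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether the members of a list differ more, in one direction, than the other genes do. The same test with a correlation estimated from the data and fry, which asks whether the members move one way on balance, stand beside it. Within each list, members were also adjusted over the list alone. The genes named are Drd2, up to 12 genes per direction, and up to 4 members per list with the smallest unadjusted p. The genes per direction are those past the adjusted threshold, filled up with the genes of smallest unadjusted p that differ by at least 0.3 on the log2 scale without overlap of the groups. Drd2, Penk, Drd1, Tac1 and Pdyn are named in the neuron lists. Other members are named where they passed the test over their list alone. Predicted genes, cDNA clones and similar symbols were counted and not named, with 1 exception that is marked where it occurs.

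The model was tested on simulated data made from the means and moderated variances of the 30176 genes, with 200 genes changed in each of 20 simulations. At 3 and 3 arrays it recovered 48.6% of genes changed by 0.5 on the log2 scale, 96.2% of those changed by 1, 99.1% at 1.5 and 99.6% at 2, and 5.06% of the calls were false. Genes varied independently in the simulation, so it does not cover correlation between genes. The adjusted threshold is easier to pass with 200 changed genes than where few differ, and 6 genes passed in the real data. There Penk, at -1.87, did not pass (adjusted p = 0.107 with limma), so the recovered shares do not carry over to the real comparison. With no change, 0 of 20 simulations called a gene list by camera at the preset correlation, and 20 of 20 called the immediate early list once its members were shifted by -0.25.

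Alternatives covered the replicate number as a block, an intensity trend with a robust prior, no moderation, renewed quantile normalisation, centring of arrays, removal of the dimmer genes, the mean of a gene's probe sets, all probe sets of the table, array weights, each array left out in turn, other thresholds and other set tests. A further one, without members that lists share, was chosen after seeing the data. The precision is limited by the number of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.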

Results

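Gene expression was measured on 6 arrays of dorsal striatum from mice at postnatal day 17, with 3 control and 3 mutant samples. Both groups lack Mapk3, and the mutants also carry Drd2Cre, which removes floxed Mapk1 in cells that make the dopamine D2 receptor. In the striatum these are the medium spiny neurons of the indirect pathway and the cholinergic interneurons. The comparison asks which transcripts differ when both ERK kinases are lost in D2 receptor cells, as seen in the whole tissue punch. Pairwise correlations between arrays over all probe sets lay between 0.9865 and 0.9941, with control replicate 2 in the lowest pairs. The positive control probe sets exceeded the negative ones with a probability between 0.805 and 0.838 per array, so signal over background was similar on the 6 arrays.

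The gene whose regulatory sequence drives Cre was compared first. Drd2 was bright on every array, at 15.5 ± 0.11 (SD, n = 3) on the log2 scale in controls and 15.7 ± 0.12 (SD, n = 3) in mutants. The difference of 0.13 did not pass the test (adjusted p = 0.998 with limma) and ran from 0.069 to 0.20 with 1 array left out. Mapk1 and Mapk3 were not analysed here, so the genotypes were not checked from the values. Of the sex-linked genes, 4 were measured. The Y-linked Kdm5d, Uty and Eif2s3y were between 9.33 and 11.25 on every array and Xist between 5.22 and 5.63, and the labels name males only.

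Of 30176 genes, 6 passed the adjusted threshold, 4 higher and 2 lower in the mutant. Ndnf, which encodes a secreted neurotrophic factor, rose by 2.15 ± 0.10 (SE) on the log2 scale, or 4.45-fold, from 8.47 ± 0.19 to 10.6 ± 0.022 (SD, n = 3 in each group, adjusted p = 0.0025). Ttc12, a tetratricopeptide repeat gene that lies close to Drd2, rose by 2.00 ± 0.13 (SE), from 6.87 ± 0.11 to 8.87 ± 0.25 (SD, n = 3 in each group, adjusted p = 0.0139). Npy1r, a neuropeptide Y receptor gene, rose by 1.40 ± 0.12 (SE, adjusted p = 0.0371). Slco5a1, of the organic anion transporter family, rose by 1.05 ± 0.096 (SE, adjusted p = 0.0465), from a control mean of 6.66. Slitrk6, which encodes a neuronal transmembrane protein with leucine-rich repeats, fell by 1.52 ± 0.14 (SE, adjusted p = 0.0451). Plxdc1, a plexin domain gene enriched in indirect pathway neurons, fell by 1.49 ± 0.12 (SE, adjusted p = 0.0371), to a mutant mean of 6.36. The median of the negative control probe sets was 6.65, so the dimmer groups of Slco5a1 and Plxdc1 were not clearly above that median. Their differences are therefore not exact sizes. The background probe sets of the array read lower, with medians between 3.69 and 3.83 per array, so the measures of background differ. For each of the 6 genes, all 3 mutant arrays lay on one side of all 3 control arrays. The count was sensitive to single arrays. It was 1, Ndnf, without control replicate 1, 2 or 3 or mutant replicate 1, and 5 without mutant replicate 3. Of those 5, Ndnf, Ttc12 and Plxdc1 are among the 6, and Gpr52 and Penk are not. Without mutant replicate 2 the count was 0 with limma, with 1050 genes at an unadjusted p under 0.05. Npy1r, Slco5a1 and Slitrk6 passed in none of these fits.

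**Figure D1:**
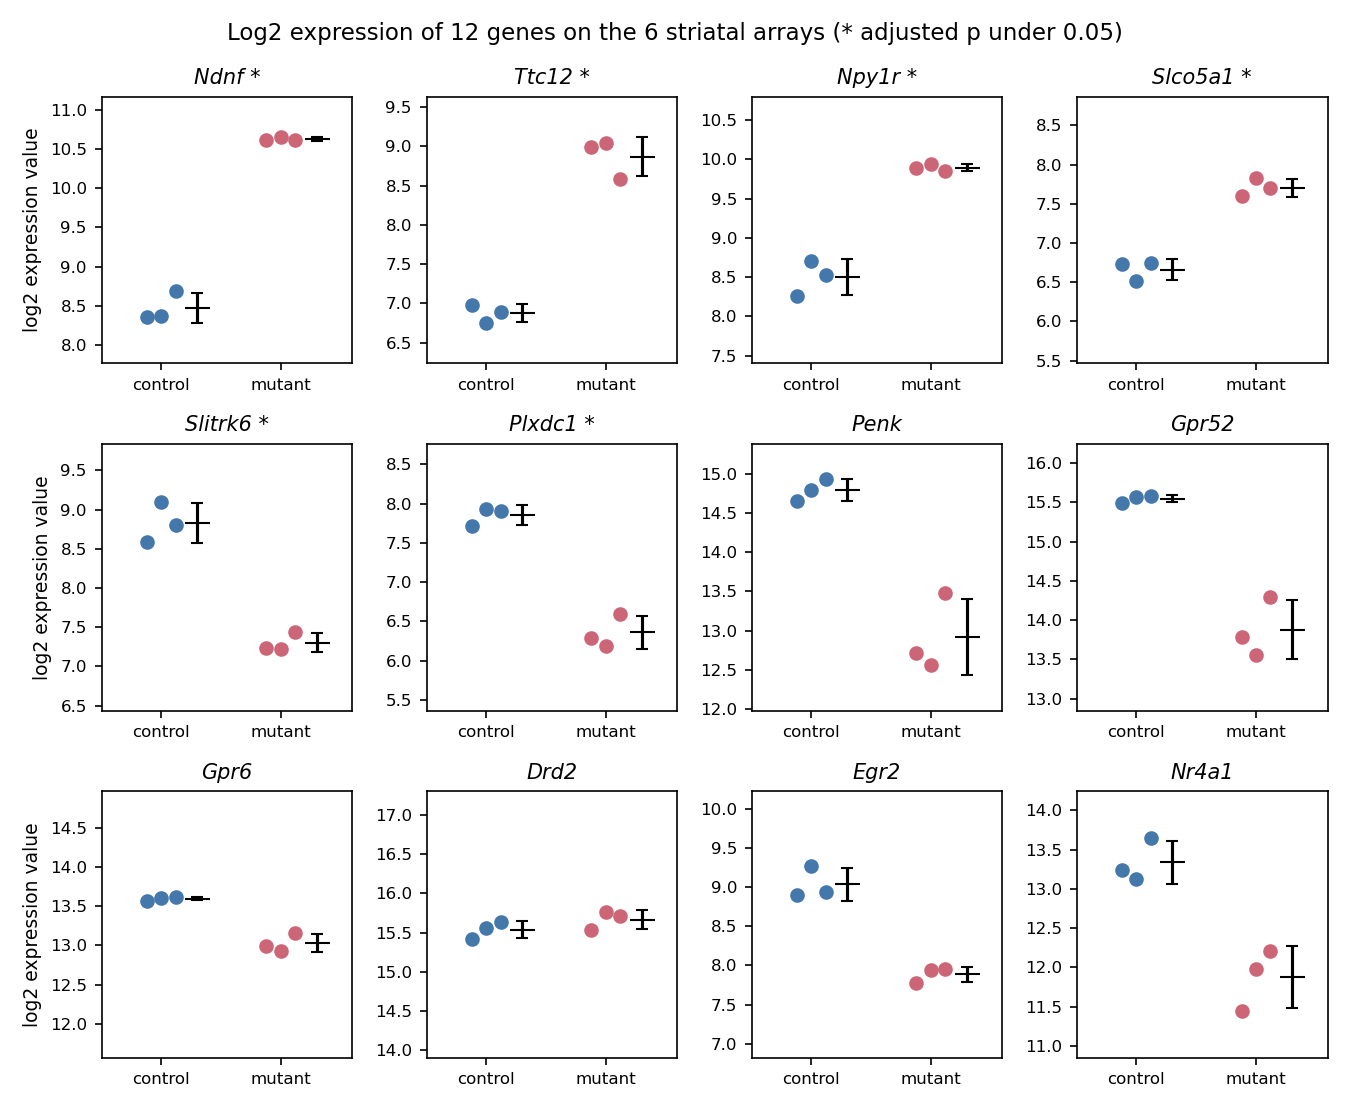
Log2 expression values of 12 genes on the 3 control (blue) and 3 mutant (red) arrays, with the mean and SD of each group in black; every panel spans the same range on its log2 axis and an asterisk marks an adjusted p under 0.05. Ndnf lies near 8.47 in controls and 10.6 in mutants, while Drd2 lies near 15.5 and 15.7.

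The genes next in rank did not pass the adjusted threshold and are given as values. On the higher side stood Gpr149, an orphan receptor gene, with a difference of 1.68 ± 0.21 (SE), and Slitrk1, a relative of Slitrk6, with 1.01 ± 0.11. The axon guidance gene Slit2 differed by 0.86 ± 0.10, the synaptic vesicle gene Sv2c by 0.85 ± 0.10 and Sulf1, which encodes an extracellular sulfatase, by 0.84 ± 0.097. The unconventional myosin gene Myo16 differed by 0.77 ± 0.075, Lypd1 by 0.72 ± 0.094 and the tropomyosin gene Tpm2 by 0.56 ± 0.073. On the lower side stood Penk, the enkephalin precursor, at -1.87 ± 0.23, the orphan receptor genes Gpr52 at -1.67 ± 0.17 and Gpr6 at -0.57 ± 0.080, and the transcription factor Egr2 at -1.14 ± 0.12. Further genes there were Myo3b at -0.92 ± 0.12, Rgs2, a regulator of G-protein signalling, at -0.89 ± 0.10, Gask1b at -0.75 ± 0.093, and the muscarinic receptor gene Chrm3 at -0.68 ± 0.078. Hectd2 stood at -0.63 ± 0.082 and the nicotinic receptor gene Chrna4 at -0.57 ± 0.081. Their adjusted p lay between 0.0551 and 0.191. The control mean of Tpm2 also lay below the negative control median, so its difference is not an exact size. At an adjusted p under 0.1 there were 14 genes, 8 higher and 6 lower.

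Over all genes the unadjusted counts were close to chance. An unadjusted p under 0.05 was reached by 1575 genes, or 5.22%, of which 644 were higher and 931 lower, and chance gives 5%. The groups did not overlap for 3042 genes, or 10.1%, where chance gives 10%. A difference of at least 1.5-fold together with an unadjusted p under 0.05 was found for 91 genes, 37 higher and 54 lower. That is 40.7% higher, against 28.8% (32 higher and 79 lower) when each array was centred on its median. The majority turned without mutant replicate 1, with 71 higher and 55 lower (56.3% higher), and over every probe set of the table, with 423 higher and 263 lower (61.7%). The median difference over all genes was -0.0024.

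Among the gene lists, 15 of 28 passed the camera test at the preset correlation, 13 lower and 2 higher. With an estimated correlation camera called 0 lists, with 8 at an unadjusted p under 0.05, and fry called 6, 5 lower and 1 higher. The 5 lower by fry were immediate early genes, ERK targets, indirect pathway markers, glutamate receptors, and dopamine and cAMP signalling. The 1 higher was the genes next to Drd2. The others of the 15 passed only camera at the preset correlation. Lists said below to fall or to be higher are those that passed that camera test. For astrocyte markers, reactive astrocyte genes, GABAergic interneuron markers and neuropeptides, none of which passed, the median, the mean and the test differed in sign. Other groupings of the 6 arrays into 3 and 3 called up to 10 lists by camera at the preset correlation.

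Markers of the indirect pathway neurons, the medium spiny neurons that make the D2 receptor, fell as a list, with a median of -0.29 over 10 measured genes (adjusted p = 5.83e-04, and adjusted p = 0.112 with an estimated correlation). Over all genes 1 member rose, Ttc12, and 1 fell, Plxdc1. When the members were adjusted over the list alone, 1 rose, Ttc12, and 5 fell, namely Plxdc1, Gpr52, Penk, Gpr6 and the kainate receptor gene Grik3 (-0.80 ± 0.12, SE). The falls were unequal in size. Penk went from 14.8 ± 0.14 to 12.9 ± 0.49 (SD, n = 3 in each group), a 3.66-fold difference, and Gpr6 from 13.6 ± 0.022 to 13.03 ± 0.12, a 1.48-fold difference. The 4 members that did not pass were Drd2 at 0.13, Upb1 at 0.06, Sp9 at 0.04 and P2ry1 at -0.01, and with 1 array left out Upb1 ran from 0.038 to 0.077 while Sp9 and P2ry1 changed sign. Without Ttc12, or with the dimmer genes left out, the median of the list was -0.57.

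Markers of the direct pathway neurons, the neighbouring class that makes the D1 receptor, did not pass (11 measured, adjusted p = 0.973), and 0 members passed adjusted over the list alone, with 1, Chrm4 at -0.22, at an unadjusted p under 0.05. Drd1 differed by 0.26 ± 0.33 (SE), Tac1 by 0.07 ± 0.10, Pdyn by -0.01 ± 0.15, Slc35d3 by -0.21 ± 0.16 and Isl1 by -0.11 ± 0.13. Sfxn1 differed by 1.24 ± 1.1, with values that varied widely within both groups. With 1 array left out Slc35d3 ran from -0.34 to -0.071, Isl1 from -0.20 to -0.0044 and Sfxn1 from 0.49 to 2.54, and Drd1, Tac1 and Pdyn changed sign. Without mutant replicate 3 this list passed as higher by camera (median 0.11, adjusted p = 0.0482). Markers shared by medium spiny neurons of both classes fell as a list, with a median of -0.14 and 18 of 21 members lower by sign (adjusted p = 1.75e-07, and adjusted p = 0.135 with an estimated correlation). The phosphatase gene Ptpn5 (-0.42 ± 0.074, SE) was the 1 member that fell adjusted over the list alone. The phosphodiesterase gene Pde1b stood at -0.25, Tmem158 at -0.43 and the adenylyl cyclase gene Adcy5 at -0.24.

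Immediate early and activity-regulated genes, which neurons switch on within minutes to hours of stimulation, gave the smallest p of the 28 lists by camera at the preset correlation. Of 41 measured members 37 were lower by sign, the median was -0.27 and the adjusted p was 1.37e-20, against an adjusted p = 0.102 with an estimated correlation. Over all genes 0 members passed, with 21 at an unadjusted p under 0.05 in limma, and adjusted over the list alone 19 fell and 0 rose. The largest of these falls were in Arc, which encodes a synaptic cytoskeletal protein (-1.53 ± 0.27, SE), and in the transcription factor genes Nr4a1 (-1.46 ± 0.21), Egr2 (-1.14 ± 0.12) and Npas4 (-1.01 ± 0.30). Npas4 stood at -0.63 without mutant replicate 1. Egr1 fell by 0.94 ± 0.14, Rgs2 by 0.89 ± 0.10, Fos by 0.83 ± 0.27 and Tiparp by 0.61 ± 0.089. The mutant mean of Fos lay below the negative control median of 6.65. The median of the list on each array, relative to the mean of all arrays, was 0.05, 0.19 and 0.16 in controls and -0.20, -0.18 and -0.07 in mutants. With the dimmer genes left out the median difference was -0.55.

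Feedback regulators and transcriptional targets of the ERK cascade also fell as a list, with a median of -0.17 over 19 genes (adjusted p = 5.24e-08, and adjusted p = 0.102 with an estimated correlation). Over all genes 0 passed, with 8 at an unadjusted p under 0.05 in limma. The 8 that fell adjusted over the list alone were Egr1, the ERK phosphatase gene Dusp6 (-0.94 ± 0.17, SE), Spry2 (-0.91 ± 0.18), Spred2 (-0.62 ± 0.12), Spred1 (-0.46 ± 0.085), Dusp5, Etv5 and Dusp14. The mutant mean of Dusp5 lay below the negative control median of 6.65. Sprouty and Spred proteins restrain the Ras and ERK cascade. The median was -0.30 without control replicate 1 and -0.46 with the dimmer genes left out. Egr1 stands on the immediate early list too, and without it the ERK target list kept an adjusted p of 7.60e-07. The members of the cascade itself and its regulators did not pass as a list (27 measured, adjusted p = 0.104), but did as lower over every probe set of the table (adjusted p = 0.02845). Adjusted over that list alone, Shc3 (-0.57), Ptpn5 (-0.42) and Rin1 (-0.48) fell and the exchange factor gene Rasgrf2 rose (1.03 ± 0.27, SE).

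**Figure D2:**
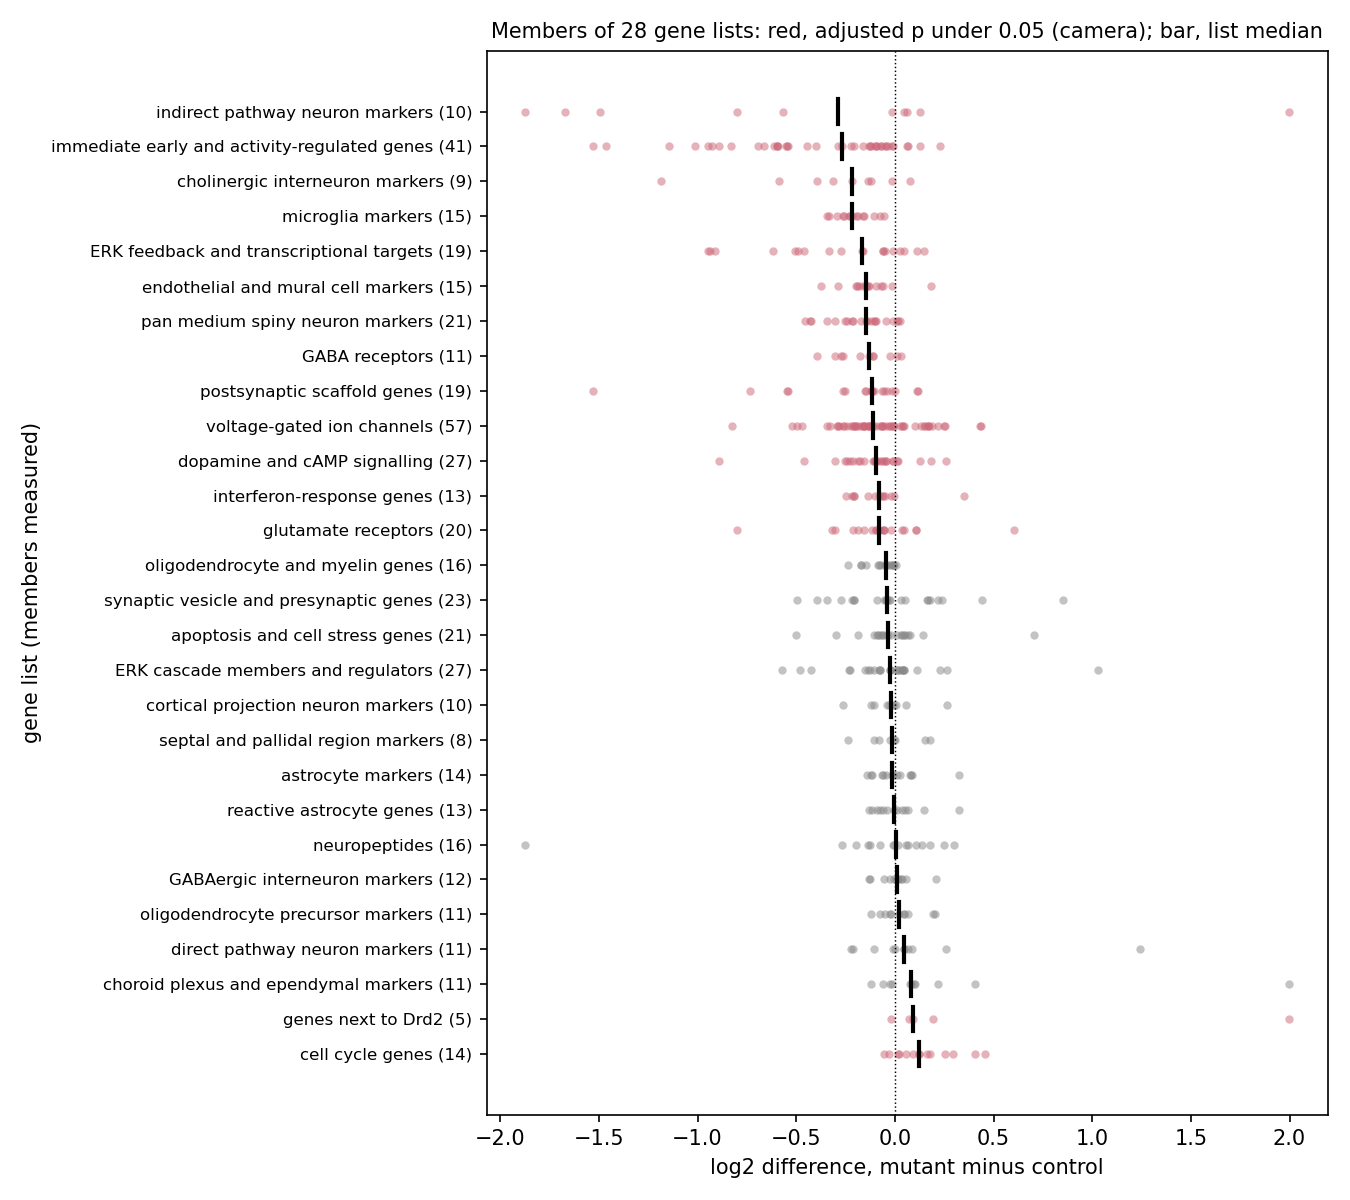
Log2 difference, mutant minus control, of each measured member (dots) of the 28 gene lists tested, with the median of each list as a black bar; lists with an adjusted p under 0.05 by camera at the preset correlation are red and the others grey. The immediate early genes spread to the left around a median of -0.27, and Ttc12 stands apart at 2.00 in the indirect pathway list and in the list of genes next to Drd2.

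Dopamine and cAMP signalling genes fell as a list (27 measured, median -0.10, adjusted p = 9.12e-06, and adjusted p = 0.102 with an estimated correlation). Rgs2 and Rgs14 (-0.46 ± 0.085, SE) were the 2 that fell adjusted over the list alone, and Pde1b at -0.25 and Rgs4 at -0.23 did not pass. With array weights the median was -0.063. Postsynaptic scaffold genes fell as a list (19 measured, median -0.12, adjusted p = 2.79e-06, and adjusted p = 0.195 with an estimated correlation). The 5 that fell adjusted over the list alone were Arc, Nrgn (-0.73), Dlgap3 (-0.55), Homer1 (-0.54) and Shank3 (-0.26). Arc and Homer1 are also on the immediate early list, and without them the list kept an adjusted p of 3.12e-04. The median was -0.074 without mutant replicate 1. Neuropeptide genes did not pass as a list (16 measured, adjusted p = 0.862), and Penk was the 1 member that fell adjusted over the list alone. Cartpt stood at 0.30, Vgf at -0.27 and Tac2 at 0.14, and Cartpt and Tac2 lay below the negative control median in both groups.

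Markers of the cholinergic interneurons, which also make the D2 receptor, fell as a list (9 measured, median -0.22, adjusted p = 5.83e-04, and adjusted p = 0.356 with an estimated correlation). Adjusted over the list alone, 2 fell, the choline transporter gene Slc5a7 (-1.19 ± 0.29, SE) and the vesicular glutamate transporter gene Slc17a8 (-0.39 ± 0.12). Slc18a3 stood at -0.59 (-0.80 to -0.34 with 1 array left out) and Slc10a4 at -0.14. The median of the list varied with single arrays, from -0.12 without control replicate 2 to -0.34 without control replicate 1 and -0.35 without mutant replicate 3. GABAergic interneuron markers did not pass (12 measured, adjusted p = 0.973), and 0 members passed over the list alone or at an unadjusted p under 0.05 in limma. Th stood at 0.21 (0.12 to 0.32 with 1 array left out) and Chodl at -0.13 (-0.18 to -0.065), while Htr3a at -0.13 and Nos1 at -0.05 changed sign. Cortical projection neuron markers (10 measured, adjusted p = 0.889) and septal and pallidal markers (8 measured, adjusted p = 0.846) did not pass either. Cux2 stood at 0.26, Lamp5 at -0.26 (-0.32 to -0.17 with 1 array left out) and Zic1 at -0.24 (-0.30 to -0.14).

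Markers of other cell types in the punch were followed as well. All 15 measured microglia markers were lower by sign, with a median of -0.22 (adjusted p = 8.43e-05, and adjusted p = 0.381 with an estimated correlation). Adjusted over the list alone 0 passed, with 1, Aif1 at -0.26, at an unadjusted p under 0.05 in limma. Tyrobp stood at -0.33 (-0.44 to -0.17 with 1 array left out), Cd68 at -0.29 (-0.44 to -0.18) and Itgam at -0.23 (-0.33 to -0.12). On the single arrays the microglia median ran from -0.07 to 0.32 in controls and from -0.27 to 0.08 in mutants, so the groups overlapped. The median difference was -0.11 without control replicate 2, -0.13 without mutant replicate 3 and -0.33 without control replicate 1. Endothelial and mural markers fell as a list (15 measured, median -0.15, adjusted p = 0.00126, and adjusted p = 0.385 with an estimated correlation), and 0 members passed over the list alone, with 2, Tagln at -0.37 (-0.54 to -0.23 with 1 array left out) and Flt1 at -0.18, at an unadjusted p under 0.05 in limma. This call was lost without mutant replicate 2 (median -0.063, adjusted p = 0.0669), and the median was -0.053 without control replicate 2. Astrocyte markers (14 measured, adjusted p = 0.922), reactive astrocyte genes (13 measured, adjusted p = 0.973) and oligodendrocyte precursor markers (11 measured, adjusted p = 0.862) did not pass, and Gfap stood at 0.33 ± 0.22 (SE), or 0.17 to 0.53 with 1 array left out. Oligodendrocyte and myelin genes did not pass (16 measured, adjusted p = 0.33). They passed in opposite directions once 1 array was left out, higher without mutant replicate 2 (median 0.088, adjusted p = 0.0161) and lower without mutant replicate 3 (median -0.18, adjusted p = 4.46e-07). With array weights they passed as lower (median -0.18, adjusted p = 4.22e-04). The list medians of mutant replicates 2 and 3, relative to the mean of all arrays, were -0.30 and 0.29.

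Choroid plexus and ependymal markers did not pass (11 measured, adjusted p = 0.104). They passed as higher by camera without control replicate 1 (adjusted p = 0.049) or mutant replicate 2 (adjusted p = 0.0259). Without mutant replicate 3 the adjusted p by camera was 0.702. Ttr, the abundant choroid plexus transcript for transthyretin, was at 12.2 in mutant replicate 3 and between 5.97 and 6.76 on the other arrays. The 3 measured blood cell genes, Alas2, S100a8 and S100a9, stood at -0.18, -0.12 and -0.01 and were not tested as a list, and the last 2 changed sign with 1 array left out. Cell cycle genes were higher as a list (14 measured, median 0.12, adjusted p = 0.00368, and adjusted p = 0.588 with an estimated correlation). Adjusted over the list alone 0 passed, and 0 reached an unadjusted p under 0.05 in limma. The list lost its call without mutant replicate 1 (adjusted p = 0.591), on which Mki67 was at 8.61 against values between 7.29 and 7.52 on the other arrays. Array weights also ended it (median 0.070, adjusted p = 0.231), and the median was 0.079 with centred arrays and 0.24 with the dimmer genes left out.

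The list of genes next to Drd2 passed in the higher direction (5 measured, median 0.09, adjusted p = 4.70e-04, and adjusted p = 0.102 with an estimated correlation), and Ttc12 was the 1 member that rose, both over all genes and adjusted over the list alone. Ankk1, between Drd2 and Ttc12 in the gene order, differed by 0.19 ± 0.087 (SE), Tmprss5 by 0.09 (0.060 to 0.11 with 1 array left out) and Ncam1 by 0.07 (0.044 to 0.096). The median was 0.049 with centred arrays.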

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

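The tests of other groupings of the arrays were planned, and those of the explanations below were chosen after the results were seen.

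A negative control probe set, outside the genes compared above, stood at 6.18 ± 0.07 (SD, n = 3) in the mutant arrays and 3.64 ± 0.25 (SD, n = 3) in the controls, a difference of 2.54 on the log2 scale. It passed the adjusted threshold over all 72688 probe sets (adjusted p = 0.0351 with limma), as the 1 of 5222 negative control probe sets to do so. The platform annotation used here gives it no gene. Both of its group means lay below the negative control median of 6.65, so its difference is not an exact size. The background probe sets had medians between 3.69 and 3.83 per array, near its control mean and below its mutant mean. Of the negative controls 9.92% had an unadjusted p under 0.05, against 4.35% of the 35318 transcript probe sets with several or no gene names, of which 0 passed the adjusted threshold and 1538 had an unadjusted p under 0.05 with limma.

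The 6 arrays can be divided in 10 ways into 3 and 3, which is too few for a share under 0.05. The real grouping gave 6 genes past the adjusted threshold and the highest other grouping 0, so 1 of 10 reached the real count. For genes with an unadjusted p under 0.05 and a 1.5-fold difference the real count was 91 and the highest other 166, and 4 of 10 groupings reached the real one. For gene lists by camera at the preset correlation the real count was 15 and the highest other 10, and 1 of 10 reached it. Of the 9 other groupings 8 called lists, and the immediate early list passed in 4 of the 9, with a smallest adjusted p of 1.87e-06 against 1.37e-20 in the real grouping.

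The rise of Ttc12 on every mutant array, next to a Drd2 that differed by 0.13 (0.069 to 0.20 with 1 array left out), has a pair of technical candidate explanations. A copy of Ttc12 carried with the Cre transgene may add transcript, and then Ankk1, which lies between Drd2 and Ttc12, could be higher too. Its difference was 0.194 (95% interval -0.0109 to 0.4), with all arrays below the median of 6.65 of the negative controls, and Gm4894, on the other side of Drd2 and named here after its value was seen, was higher by 0.40 ± 0.076 (SE) at a similarly low level, so this explanation stays open. A chromosome segment of another strain around Drd2 may also change neighbouring probe sets. Of 17 measured neighbours within 10 places of Drd2, Ttc12 left out, 1 had an unadjusted p under 0.05, with a median absolute difference of 0.0746 against 0.0697 for all genes, which neither shows nor excludes a segment, and since Cre and group coincide, an effect of losing ERK in these cells cannot be told apart from either.

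Indirect pathway markers were lower by unequal amounts, Penk by far more than Gpr6. Fewer indirect pathway neurons in the mutant punches could lower such markers. Equal falls would follow only if each marker were made by these neurons alone and the array read it in proportion. Penk minus Gpr6, a pair taken after their unequal falls were seen, differed between groups by -1.31 ± 0.226 (SE over arrays). The 6 markers with a control mean of at least 8, Drd2 and Ttc12 left out, were heterogeneous (Cochran's Q = 145). Among them Sp9 stood at 0.04 and P2ry1 at -0.01. Cochran's Q treats the markers as independent, although they share the same arrays. The markers thus had no common fall, but neither condition was tested, so this does not decide on cell loss. Normalization between arrays could also shift bright genes. The smallest fall of Penk, Gpr52 and Plxdc1 under renewed quantile normalisation or centring was -1.535, in the dim Plxdc1. For the bright Penk and Gpr52 it was -1.66. The median difference over all genes moved only to -0.0256 under the first scaling and -0.0442 under the second, far less than these falls. Such small shifts do not decide on the normalisation already in the deposited values. The loss of ERK in D2 receptor cells, which the design names, stays open and was not tested apart from cell loss or normalisation. Cre and group coincide, so the loss of ERK cannot be told apart from an effect of Cre itself.

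Immediate early genes were lower as a list at the preset correlation (adjusted p = 1.37e-20, and adjusted p = 0.102 with an estimated correlation). Fewer medium spiny neurons in the mutant punches could lower them. The mean of the immediate early genes fell further than the mean of the shared medium spiny neuron markers, by -0.226 ± 0.0299 (SE over arrays). The comparison was chosen after the immediate early list had given the smallest p by camera, and neuron loss need not lower both lists alike. It therefore does not decide on a loss of neurons. Choroid plexus tissue in mutant replicate 3, where Ttr was at 12.2, may dilute neuronal transcripts, yet without that array the median of the list was -0.2673, against -0.27 with it. The order and speed of dissection, to which these genes respond, are not given in the labels and stay open. The loss of ERK in D2 receptor cells stays open as well and was not tested apart from dissection or a loss of neurons. Since Cre and group coincide, an effect of Cre itself cannot be told apart from it either.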

How the results depend on the processing

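Alternatives were planned, except the removal of members that lists share, and 1 cause, fewer arrays, is plain where an array is left out; the other causes were not tested. The 6 genes past the adjusted threshold became 1 without moderation (none of the 6), 3 after renewed quantile normalisation, 2 over every probe set (Ndnf and a negative control), 19 with array weights (including the 6), 14 at an adjusted p under 0.1, and 0 to 5 with 1 array left out. The count lay between 6 and 8 with a trend and robust prior, centring, the dimmer genes left out or probe sets averaged. All 6 remained in each of these settings, and at most 3 of them with 1 array left out. The 91 genes at an unadjusted p under 0.05 and 1.5-fold became 686 over every probe set and 92 to 178 with 1 array left out. Centring the arrays changed their split from 37 higher and 54 lower to 32 and 79. The 15 lists became 0 with an estimated correlation and 6 by fry, stayed between 12 and 16 otherwise, and none of the 15 turned its direction where tested. With the dimmer genes left out 26 lists were tested, and without shared members 27. The list of genes next to Drd2 was not tested in either setting. Oligodendrocyte and myelin genes, not among the 15, passed as higher without mutant replicate 2 and as lower without mutant replicate 3 and with array weights. Lists lost most often were interferon-response genes and glutamate receptors. Of the 114 genes whose difference or direction the text gives, 9 changed sign in some setting, each with an adjusted p of at least 0.998 in the test reported above. With 1 array left out Drd1 ranged from -0.007133 to 0.6224, Tac1 from -0.009167 to 0.1343, Pdyn from -0.1124 to 0.1222, P2ry1 from -0.06726 to 0.08395, Sp9 from -0.0265 to 0.1334, Nos1 from -0.175 to 0.02534, Htr3a from -0.2479 to 0.005528, S100a8 from -0.3842 to 0.2027 and S100a9 from -0.06643 to 0.04669. With array weights Pdyn was at 0.1184 and P2ry1 at 0.003957.

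The replicate numbers gave no clear pairing of the samples. Deviations of arrays with the same number correlated at -0.0575, -0.146 and 0.245. Control replicate 1 correlated best with mutant replicate 2 (0.2) and control replicate 2 with mutant replicate 1 (0.245). Deviations within so small a group depend on each other, so these correlations cannot exclude a pairing. A block by another pairing was not fitted. With the replicate number as a block, 4 genes passed, of which 2, Ndnf and Ttc12, are among the 6, with 97 genes at an unadjusted p under 0.05 and 1.5-fold and 15 lists. The planned Mapk1 result could not be computed under any setting, and camera was not run without moderation. Low signal limits the dim genes: 16408 genes had a mean below the median of the negative controls, 6.65. That median is a strict mark. The gene medians of the arrays lay between 6.21 and 6.25, and the background probe sets read lower still.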

Other observations

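Tests here use the planned lists; Chat was chosen after its values were seen.

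Genes that set the excitability of neurons went both ways. The list named voltage-gated ion channels also holds auxiliary subunits and channels not gated by voltage. Voltage-gated ion channels were lower as a list (57 measured, median -0.11, adjusted p = 6.02e-04, and adjusted p = 0.368 with an estimated correlation), a call lost without control replicate 3 (adjusted p = 0.0589) or mutant replicate 1 (median -0.048, adjusted p = 0.168). Adjusted over the list alone, 2 rose, the potassium channel gene Kcnh1 (0.43 ± 0.080, SE) and the pacemaker channel gene Hcn4 (0.44 ± 0.083). The 7 that fell include the inward rectifier gene Kcnj2 (-0.83 ± 0.14), the leak channel gene Kcnk2 (-0.49), Kcnv1 (-0.47), the sodium channel genes Scn3a (-0.33) and Scn3b (-0.29), and Cacng3 (-0.52) and Cacng4 (-0.29), which encode auxiliary subunits.

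Glutamate receptor genes were lower as a list (20 measured, median -0.08, adjusted p = 0.0177, and adjusted p = 0.161 with an estimated correlation). The call was lost without control replicate 1 (adjusted p = 0.0534), control replicate 3 (adjusted p = 0.0785) or mutant replicate 1 (adjusted p = 0.0589), after renewed quantile normalisation (adjusted p = 0.129), with the dimmer genes left out (adjusted p = 0.0647), and without Grik3, which the indirect pathway list shares (adjusted p = 0.0983). Adjusted over the list alone, the kainate receptor gene Grik4 rose (0.60 ± 0.087, SE), and its relative Grik3 (-0.80 ± 0.12) and the metabotropic receptor gene Grm5 (-0.30 ± 0.065) fell. Gria2 stood at -0.19. The median was -0.12 with centred arrays. GABA receptor genes fell as a list (11 measured, median -0.13, adjusted p = 6.02e-04, and adjusted p = 0.102 with an estimated correlation), with Gabra4 (-0.39 ± 0.076, SE) past the threshold over the list alone and Gabrb1 at -0.27 and Gabbr2 at -0.26 not past it. The median was -0.074 after renewed quantile normalisation. Presynaptic genes did not pass as a list (23 measured, adjusted p = 0.922), and Sv2c was the 1 member that rose adjusted over the list alone. Syn3 stood at 0.44, Syt4 at -0.34 and Rims1 at -0.22.

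Apoptosis and cell stress genes did not pass as a list (21 measured, adjusted p = 0.862). Adjusted over the list alone, Bcl2, which encodes a survival factor, fell (-0.50 ± 0.11, SE), and Cdkn1a stood at 0.71 ± 0.26 and Trib3 at 0.14. Interferon-response genes were lower as a list (13 measured, median -0.08, adjusted p = 0.0322, and adjusted p = 0.356 with an estimated correlation), while Ifit1, the 1 member past the threshold over the list alone, rose (0.35 ± 0.084). Bst2 stood at -0.25 (-0.32 to -0.12 with 1 array left out) and Oasl2 at -0.21 (-0.27 to -0.14). Ifit1, Bst2 and Oasl2 lay below the negative control median of 6.65 in both groups, so their differences are not exact sizes. The rise of Ifit1 is thus between dim values below that median. The call of the list was lost without control replicate 1 (adjusted p = 0.185), control replicate 3 (adjusted p = 0.0753), mutant replicate 2 (adjusted p = 0.0669) or mutant replicate 3 (adjusted p = 0.234), and with the dimmer genes left out (adjusted p = 0.133). The median was -0.12 with centred arrays.

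The neighbouring genes Sfxn1 and Drd1 varied widely within both groups. Sfxn1 was at 13.2, 13.2 and 11.1 on the control arrays and 15.2, 14.8 and 11.1 on the mutant arrays. Drd1 was at 13.95, 14.20 and 13.46 and at 14.66, 14.32 and 13.40 on the same arrays.

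Chat, the choline acetyltransferase gene that marks cholinergic interneurons, was at 7.69, 8.48 and 7.88 on the control arrays and 7.63, 7.53 and 7.95 on the mutant arrays. The choline transporter gene Slc5a7, which fell when adjusted over the list of cholinergic markers, was at 9.21, 9.84 and 9.14 and at 8.35, 7.63 and 8.67 on the same arrays.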
